A study of Mus musculus with 16 samples.

How the data were processed

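The deposited files hold whole-number read counts per gene for 16 polyA RNA libraries, 1 file per library. Per the labels' protocols, each library pooled periaqueductal gray punches of 2 male mice, RNA was extracted with TRIzol, and libraries were made with the TruSeq RNA v2 kit, which does not mark the strand. The counts were made with HTSeq on the mm10 build, per the submitters' processing notes, which also name limma; the aligner, annotation release and strand setting are not given in the sources used here. HTSeq's own tallies of reads outside genes, ambiguous or not uniquely placed came to 38.2 to 40.6% of the total and stayed out of library sizes and tests. All 37 mitochondrially encoded genes stood at 0 in every library, so a list of them set as a sign of RNA quality could not be tested. Because the strand was not kept by the kit, reads of overlapping genes on opposite strands cannot be told apart.

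Groups were taken from the genotype and treatment labels, 4 libraries each, which the labels call biological replicates. Gene symbols and positions came from GENCODE M21 on GRCm38, the same assembly as mm10; 37607 of 38924 gene identifiers matched. Replicates of a group differed beyond sampling noise in every pair (chi-square per gene of at least 3.73), so none was treated as a duplicate. Totals over genes ranged from 19.1 to 55.0 M (mega counts). Counts of 18111 genes were simulated with the real means and library sizes and 50 changed genes per fold size. The changed genes had a mean above 1 count per mega counts of the library, so recovery among lower genes was not tried. Genes were drawn independently, without the shared structure of the real libraries. In the wild-type morphine comparison, edgeR recovered 60% of 1.25-fold, 72% of 1.5-fold and 96% of 2-fold changes, and 15 of its 179 calls were false (8.38%). In the naive genotype comparison it recovered 50%, 68% and 94%, and 8 of 164 calls were false (4.88%).

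The comparisons, tests, gene lists and naming rule were set before the data were examined. Genes were kept with edgeR's filterByExpr (minimum count 10), scaled with TMM, and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust) in 1 fit of all 16 libraries with a coefficient per group; the common biological coefficient of variation was 0.0835. Benjamini-Hochberg adjusted p under 0.05 was the threshold. There were 7 comparisons: morphine against naive in each genotype, genotype within each treatment, their interaction, and both averages. Values are log2 fold changes ± SE, and CPM, counts per mega counts of the library, are TMM-scaled means ± SD.

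In each of the first 4 comparisons the named genes were, among called genes with a mean log2 CPM of at least 1 that were not predicted genes or pseudogenes, up to 12 with the largest positive and 12 with the largest negative log2 fold change, from which the text takes a part. That part was chosen after the values were seen, and leaves out some genes whose call changed when 1 library was left out. Some genes that the rule would name are not reported here. For the interaction and averages they were the 6 with the smallest p in each direction. Up to 4 members of a described list with the smallest p, and any RGS or opioid receptor and peptide gene, could also be named. Gene lists with at least 3 tested members, 40 in all, were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. No list passed with an estimated correlation in any comparison. They included glucocorticoid-induced, immediate early, endoplasmic reticulum stress, clock, opioid, RGS, Wnt component and Wnt target genes, neuropeptides, and markers of serotonin and dopamine neurons, oligodendrocytes, microglia, endothelial cells, pericytes and meningeal fibroblasts. A list of genes within 10 Mb of Rgs20 was made from the annotation. List scores are the mean over members of log2 CPM centred over the libraries, compared by exact permutation. The position test counted called genes with another within 1 Mb against 10000 random sets of tested genes. It was repeated within and outside chromosome 1 after its result was seen.

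Alternatives set beforehand were DESeq2's size factors, no filter, a stricter filter (at least 1 CPM in 8 libraries), DESeq2's Wald test (1.42.0), limma-voom, only the groups compared, a replicate block, 1 surrogate variable (sva 3.50.0), and leaving out each library. Added after the data were seen were the serotonin score and the serotonin and meningeal scores as covariates, leaving out wild-type naive 2 and knockout morphine 3 together, and thinning all libraries to the smallest total. Genes with too few counts were left out, smaller simulated changes than 1.25-fold were not tried, and exon-level changes cannot be read from these counts.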

Results

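Gene expression was measured by polyA RNA sequencing in the periaqueductal gray of male mice, a midbrain region that holds opioid-sensitive neurons of the descending pain control pathway. The series asks how tolerance to morphine, an opioid analgesic, and the protein RGSz1 shape gene expression there. RGSz1 is encoded by Rgs20 and belongs to the RGS proteins, which speed up the switching off of G protein signals. The 16 libraries fell into 4 groups of 4: wild-type naive, wild-type morphine, knockout naive and knockout morphine. No group is labelled as given a vehicle, so effects of handling and of giving the drug cannot be told apart from those of morphine. Each library pooled tissue punches from 2 animals. The total count over genes ranged from 19.1 M (mega counts, knockout morphine 2) to 55.0 M (knockout naive 1). Group means ± SD were 41.8 ± 11.1 M in wild-type naive, 37.2 ± 11.5 M in wild-type morphine, 42.8 ± 11.3 M in knockout naive and 27.4 ± 9.51 M in knockout morphine libraries (n = 4 each). Of the 38924 genes in the files, 18111 had enough counts to be tested.

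Rgs20, the targeted gene, was not lower in the libraries labelled knockout. It lies on the minus strand of chromosome 1 at 4909576 to 5070285 (GRCm38) and overlaps the start of Atp6v1h on the other strand. Its normalised level was 12.8 ± 0.82 CPM (counts scaled per mega counts of the library) in wild-type naive libraries, 13.1 ± 1.04 in wild-type morphine, 12.6 ± 0.95 in knockout naive and 12.1 ± 0.67 in knockout morphine (mean ± SD, n = 4). The log2 fold change of the libraries labelled knockout against wild type was -0.02 ± 0.07 (SE) in naive and -0.11 ± 0.07 in morphine-treated libraries (adjusted p = 0.943 and 0.669, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 95% interval of the averaged difference had its lower end at 88.6% of the wild-type level. The counts are 1 number per gene, so they do not show which exons the reads came from. They therefore neither bear out nor contradict the genotype label. Because Rgs20 counts do not separate the labels, the groups are called libraries labelled knockout below. A direction between genotypes is a direction between labels.

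**Figure D1:**
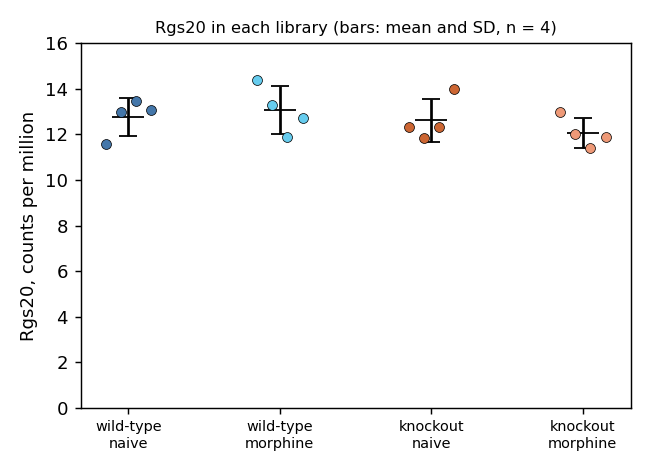
Rgs20 in CPM (vertical axis, from 0) in each of the 16 libraries, by group; points are libraries and bars the mean and SD of 4. The libraries labelled knockout, at means of 12.6 and 12.1, overlap the wild-type libraries, at 12.8 and 13.1.

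With morphine, wild-type libraries showed higher levels of genes that glucocorticoid hormones induce and lower levels of several genes of blood vessels, microglia and Wnt signalling. The largest increase among the expressed named genes was that of Cdkn1a, which encodes a cell cycle inhibitor, with a log2 fold change of 2.23 ± 0.16, or 4.70-fold. Next were Plin4, a lipid droplet protein (2.16 ± 0.33), the transcription factor Zbtb16 (1.94 ± 0.21) and Pdk4, a kinase that restrains pyruvate use (1.69 ± 0.21). The largest decreases named were those of the transcription factor Foxb1 (-1.65 ± 0.27) and the death ligand Tnfsf10 (-1.48 ± 0.23). In all, 424 genes were higher and 374 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group).

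Of the 31 measured glucocorticoid-induced genes, 22 rose in wild-type libraries (24 adjusted over the list alone), with a median log2 fold change of 0.72. The list stood apart from other genes by camera (adjusted p = 3.77e-33), and narrowly missed the threshold otherwise (adjusted p = 0.0503 with an estimated correlation). Arrdc2 rose by 1.47 ± 0.13 on the log2 scale, Fkbp5, a co-chaperone of the glucocorticoid receptor, by 1.29 ± 0.13, the kinase gene Sgk1 by 1.34 ± 0.23 and Hif3a by 1.31 ± 0.18. Klf15 and Errfi1 rose by 0.66 ± 0.07 and 0.70 ± 0.08. The serotonin marker score, a measure of neurons of the neighbouring dorsal raphe, was 0.41 ± 0.17 in wild-type morphine and -0.21 ± 0.70 in wild-type naive libraries (mean ± SD, n = 4, exact permutation test, two-sided p = 0.171).

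Among 37 measured immediate early genes, which respond quickly to cell activity, 8 rose and 3 fell with morphine in wild-type libraries (10 and 7 adjusted over the list alone; camera adjusted p = 0.0346, and adjusted p = 0.573 with an estimated correlation). Fosb (1.40 ± 0.18), Gadd45g (0.78 ± 0.10) and Homer1, a postsynaptic scaffold gene (0.40 ± 0.06), were among the higher ones. The 11 calls became 7 without wild-type naive 2 or wild-type morphine 2. Of 23 endoplasmic reticulum stress genes, 3 rose (5 adjusted over the list alone), including Herpud1 (0.24 ± 0.04) and Xbp1 (0.21 ± 0.05); camera gave an adjusted p = 6.14e-05, which became an adjusted p = 0.536 with an estimated correlation. The clock genes were split, with 2 higher and 2 lower of 20 (3 and 4 adjusted over the list alone; camera adjusted p = 0.73, lower, as the mean of -0.016, while the median was 0.033): Per1 rose by 0.37 ± 0.10 and Nr1d1 fell by 0.43 ± 0.07.

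Of 23 measured targets of Wnt/beta-catenin signalling, 7 fell and 1 rose with morphine in wild-type libraries (12 and 2 adjusted over the list alone), and the median log2 fold change was -0.19 (camera adjusted p = 2.09e-05, but adjusted p = 0.224 with an estimated correlation). The members that moved included Rnf43, which limits Wnt receptors (-1.05 ± 0.13), Apcdd1, a Wnt inhibitor (-0.42 ± 0.08), Sox9, also in the astrocyte list (-0.99 ± 0.13), and Cldn5, a tight junction gene also in the endothelial list (-1.09 ± 0.16). Of 90 pathway components, 2 rose and 4 fell (4 and 9 adjusted over the list alone): the receptor Fzd2 (0.82 ± 0.13) was higher, while Bcl9l (-0.35 ± 0.05) and Wnt7a (-0.51 ± 0.12) were lower. For the components, camera gave an adjusted p = 0.0231 and an adjusted p = 0.536 with an estimated correlation. Jag1, a Notch ligand, was also lower (-0.94 ± 0.10).

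Some markers of vessels and microglia were lower in the wild-type morphine libraries. Of 10 endothelial markers, 3 fell, both over all genes and adjusted over the list alone (median -0.28): Cldn5, the transporter Slco1a4 (-0.34 ± 0.08) and the receptor Tek (-0.42 ± 0.11). Kdr, a receptor for vascular growth factor (-0.96 ± 0.13), and Clec14a (-0.92 ± 0.19) were lower too. The 3 endothelial calls became 1 without wild-type naive 1 or 2 or wild-type morphine 1, 2 or 4, and the microglia call became 2 without wild-type naive 1 or wild-type morphine 1 and 3 without wild-type naive 4. Of 10 microglia markers, 1 fell over all genes tested and 6 adjusted over the list alone (median -0.25), with Cx3cr1, the fractalkine receptor, at -0.61 ± 0.07. P2ry13, a purine receptor of microglia (-1.09 ± 0.15), and Pdgfrb, a pericyte receptor (-0.73 ± 0.08), were also lower. Camera gave an adjusted p = 0.00259 for the endothelial and 0.000339 for the microglia list, and both had an adjusted p = 0.536 with an estimated correlation. The list scores were lower with morphine for endothelial (-0.17 against 0.12), microglia (-0.12 against 0.10), red blood cell (-0.22 against 0.29) and astrocyte markers (-0.065 against 0.079). Each had an exact permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.163 after adjustment over 40 lists. Of 5 red blood cell markers 0 passed edgeR's test (3 lower adjusted over the list alone), and of 10 astrocyte markers 1 fell, also adjusted over the list alone. The meningeal fibroblast markers had a median of -1.32 in the same comparison with 0 of 10 members past edgeR's threshold, and the library wild-type naive 2 alone had a meningeal score of 2.41.

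Of 8 opioid receptor and peptide genes, 0 passed edgeR's test, also adjusted over the list alone: the mu receptor gene Oprm1 was at 0.00 ± 0.09, the enkephalin gene Penk at 0.13 ± 0.06 (adjusted p = 0.249) and the dynorphin gene Pdyn at 0.60 ± 0.27 (adjusted p = 0.225). Of 53 opioid signalling genes, 1 rose, Crem (0.35 ± 0.06), and of 19 RGS genes, 1 rose, Rgs2 (0.25 ± 0.05), with the same counts adjusted over the list alone. The score of the receptors and peptides was higher with morphine by 0.16 (exact permutation p = 0.0286, 0.163 after adjustment). Camera gave adjusted p = 0.0463 for them (adjusted p = 0.536 with an estimated correlation), 0.385 for the signalling genes and 0.328 for the RGS genes. The count of 798 changed genes rested on single libraries: it was 493 without wild-type naive 2, 378 without wild-type naive 3 and 1252 without wild-type naive 4. It was 427 without wild-type morphine 1, 389 without wild-type morphine 2 and 493 without wild-type morphine 4. Calls of 5 genes named above were each lost without at least 1 library. Slco1a4 lost its call without wild-type naive 1 or 2 or morphine 1, 2 or 4 (edgeR adjusted p up to 0.0789), and Tek without those or naive 3 (up to 0.111). Xbp1 lost its call without naive 1, 2 or 3 or morphine 1, 2 or 4 (up to 0.0899), Wnt7a without naive 2 or 3 or morphine 2 (up to 0.0682), and Per1 without any library but naive 2 (up to 0.108).

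In the libraries labelled knockout, morphine went with higher glucocorticoid-induced and immediate early genes, higher serotonin neuron markers and lower oligodendrocyte markers. The vesicular glutamate transporter gene Slc17a8 led the higher named genes (3.31 ± 0.66). Tph2 (2.60 ± 0.68), the serotonin-synthesising enzyme of the brain, Slc6a4, the serotonin transporter (2.51 ± 0.66), Slc18a2 (2.16 ± 0.53) and Gch1 (2.03 ± 0.47) followed. Cdkn1a rose by 1.98 ± 0.16 on the log2 scale, 3.95-fold. In all, 1026 genes were higher and 1056 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group).

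Of 10 measured serotonin neuron markers, 9 rose in the libraries labelled knockout (10 adjusted over the list alone), with a median log2 fold change of 1.79 (camera adjusted p = 1.64e-08; adjusted p = 0.448 with an estimated correlation). Ddc (1.92 ± 0.45), En1 (1.66 ± 0.33), Maob (0.99 ± 0.20) and Htr1a (0.51 ± 0.12) were among the other higher members. The score of the list was 0.71 ± 0.69 in knockout morphine and -0.91 ± 0.56 in knockout naive libraries (mean ± SD, n = 4, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.0952 after Benjamini-Hochberg adjustment over 40 lists). The 9 members became 2 without knockout naive 2, 5 without knockout naive 3, 3 without knockout morphine 2 and 3 without knockout morphine 4, so the number of serotonin calls depended on these libraries. Other neuron lists went both ways. The score difference was 2.08 for noradrenergic (exact permutation p = 0.0857), 1.39 for motor and cholinergic (p = 0.0571), 0.51 for glutamatergic (p = 0.0286, 0.0952 after adjustment) and 0.046 for general neuron markers (p = 0.457). It was -0.14 for forebrain (exact permutation p = 0.0286, 0.0952 after adjustment), -0.061 for GABAergic (p = 0.371) and -0.20 for tectum markers (p = 0.257). The glutamatergic score is a mean over 6 tested members. Among them is Slc17a8, which led the higher named genes, so that gene weighs heavily in the glutamatergic difference. Knockout morphine 2 had the highest noradrenergic score, 3.36. Tph2 had an edgeR adjusted p of 0.0287, which rose to 0.0851 without knockout naive 2, 0.0749 without knockout morphine 2 and 0.0754 without knockout morphine 4, and its call was also lost without knockout naive 1 or 3. Slc6a4 lost its call without the same libraries (up to 0.0863), Slc18a2 without knockout naive 2 or 3 or morphine 2 or 4 (up to 0.0715). Ddc lost its call without knockout naive 2 or morphine 2 or 4 (up to 0.0591), Gch1 without knockout naive 2 or morphine 4 (up to 0.0521) and Htr1a without knockout naive 2 (0.0557).

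Of the 31 glucocorticoid-induced genes, 24 rose with morphine in the libraries labelled knockout (26 higher and 1 lower adjusted over the list alone), with a median of 0.81 (camera adjusted p = 4.65e-20; adjusted p = 0.271 with an estimated correlation). Fkbp5 rose by 1.10 ± 0.13, Arrdc2 by 0.93 ± 0.13 and Nfkbia, an inhibitor of NF-kappa-B, by 0.81 ± 0.11. With the serotonin score as a covariate the list's median was 0.73 and 3 members were called, because the median standard error rose from 0.13 to 0.20. Of 37 immediate early genes, 13 rose and 2 fell (18 and 3 adjusted over the list alone; camera adjusted p = 8.36e-05; adjusted p = 0.488 with an estimated correlation), among them Fosb (1.54 ± 0.19), Gadd45g (0.87 ± 0.10), Csrnp1 (0.64 ± 0.10) and the phosphatase gene Dusp6 (-0.46 ± 0.07). The 15 calls became 8 without knockout naive 2. With the serotonin score as a covariate the median of the immediate early genes went from 0.23 to 0.33. In that fit 5 of them were called, and their median standard error rose from 0.14 to 0.20. Of 23 endoplasmic reticulum stress genes, 10 rose (15 adjusted over the list alone; camera adjusted p = 4.12e-08; adjusted p = 0.448 with an estimated correlation). The 10 became 6 without knockout naive 2 or 4 or knockout morphine 1 or 2. With the serotonin score as a covariate the median of this list went from 0.14 to 0.12. In that fit 0 members were called, and the median standard error rose from 0.048 to 0.075. Among the 10 were the chaperones Hspa5 (0.34 ± 0.07) and Hyou1 (0.19 ± 0.04) and the disulfide isomerases Pdia6 (0.24 ± 0.05) and Pdia3 (0.19 ± 0.04).

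Of 11 oligodendrocyte markers, 7 fell with morphine in the libraries labelled knockout (9 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 4.12e-08; adjusted p = 0.488 with an estimated correlation). The myelin genes Mag (-0.69 ± 0.13), Ugt8a (-0.61 ± 0.12), Opalin (-0.53 ± 0.10) and Cnp (-0.43 ± 0.10) were among them. The list's score was lower in the group in which the serotonin score was higher. With the serotonin score as a covariate, however, the list's median did not shrink: it was -0.58, and 11 of 11 members kept their sign. In that fit 1 member was called, and the median standard error rose from 0.13 to 0.20. The 7 members became 3 without knockout naive 2, 4 without knockout naive 4, and 3 without knockout morphine 2 or 4. The call of Cnp was lost without knockout naive 2 or morphine 2 or 4 (edgeR adjusted p up to 0.0565). Adamtsl4 (-1.06 ± 0.12), Adamts4 (-0.94 ± 0.11), a protease gene of oligodendrocytes, and the receptor Erbb3 (-0.92 ± 0.16) were lower, as was Tnfsf10 (-1.41 ± 0.23). Of 10 endothelial markers, 3 fell (4 adjusted over the list alone): Cldn5 (-0.79 ± 0.16), Slco1a4 (-0.40 ± 0.08) and Tek (-0.45 ± 0.11), whose call was lost without knockout naive 2 or morphine 1 (up to 0.0544). Of 10 microglia markers, 1 fell, also adjusted over the list alone, namely Cx3cr1 (-0.49 ± 0.07). Camera gave an adjusted p = 0.00697 for endothelial and 0.00983 for microglia markers, with an adjusted p = 0.507 and an adjusted p = 0.488 with an estimated correlation.

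Of 8 opioid receptor and peptide genes, 2 rose with morphine in the libraries labelled knockout, also adjusted over the list alone: Penk by 0.36 ± 0.06 and Pdyn by 1.24 ± 0.27, or 2.36-fold (camera adjusted p = 0.0968 for the list). The score difference was 0.20 (exact permutation p = 0.0286, 0.0952 after adjustment), against 0.16 in wild-type libraries, and the interaction of the list did not pass (camera adjusted p = 0.879). Oprm1 was at -0.04 ± 0.09 (adjusted p = 0.866). Of 53 opioid signalling genes, 8 rose and 3 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.00697; adjusted p = 0.488 with an estimated correlation), including the G protein subunit genes Gng2 (0.29 ± 0.05) and Gng4 (0.30 ± 0.06), Crem (0.32 ± 0.06) and the adenylyl cyclase gene Adcy1 (-0.23 ± 0.05). Of 27 neuropeptide genes, 5 rose (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000646; adjusted p = 0.448 with an estimated correlation), with Scg2 at 0.52 ± 0.11. The 5 became 1 to 3 without any 1 of knockout naive 1, 2, 3 or 4 or knockout morphine 2 or 4. With the serotonin score as a covariate the neuropeptide median went from 0.30 to 0.075 and 0 members were called. The median standard error of these genes rose from 0.20 to 0.28 in that fit. Among 19 RGS genes, Rgs2 (0.34 ± 0.05) and Rgs9 (0.27 ± 0.06) rose and Rgs5 was lower (-0.36 ± 0.10), and the same numbers passed adjusted over the list alone (camera adjusted p = 0.618). Rgs9 lost its call without knockout naive 2 or knockout morphine 4 (edgeR adjusted p up to 0.0509), and Rgs5 without knockout naive 2, 3 or 4 or knockout morphine 1, 2 or 4 (up to 0.108).

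Of 23 Wnt targets, 5 fell and 1 rose in this comparison (8 and 3 adjusted over the list alone), with a median of -0.19. Camera gave an adjusted p = 0.0135, and an adjusted p = 0.488 with an estimated correlation. Among these members were Nkd1 (-0.45 ± 0.09), Rnf43 (-0.56 ± 0.13) and Tnfrsf19 (-0.19 ± 0.05). With the serotonin score as a covariate the median of the Wnt targets was -0.056, 17 of 23 kept their sign and the 6 calls became 1. Their median standard error rose from 0.097 to 0.15. Of 90 Wnt components, 5 rose and 6 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.239, lower, as the median of -0.029, while the mean was 0.014), with Dvl3 (-0.24 ± 0.04), Bcl9l (-0.32 ± 0.06) and Prickle1 (-0.28 ± 0.05) lower and Rspo2 (0.92 ± 0.21) higher. The clock genes Nr1d1 (-0.52 ± 0.07) and Bhlhe40 (-0.40 ± 0.05) were among 4 lower and 1 higher of 20, with the same counts adjusted over the list alone (camera adjusted p = 0.0968). Of 8 dopamine neuron markers, 3 rose (4 adjusted over the list alone; camera adjusted p = 0.0699). The calls of Chrna6 and Slc6a3 were both lost without knockout naive 2 or knockout morphine 4 (edgeR adjusted p up to 0.0892 and 0.108). That of Chrna6 was also lost without knockout naive 1 or 3 or knockout morphine 2 (up to 0.0975), and that of Slc6a3 without knockout naive 4 (0.0672). The count of 2082 changed genes was 1037 without knockout naive 2, 1302 without knockout naive 4, 1248 without knockout morphine 2 and 1301 without knockout morphine 4. It was 306 with the serotonin score as a covariate and 3 with the serotonin and meningeal scores, fits whose covariates overlap with the groups.

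The direction of the morphine changes was shared between the genotypes, with no library in common. Across the 2495 genes called in either, the log2 fold changes correlated with a Pearson r of 0.646 and a Spearman rho of 0.703, against 0.179 and 0.274 over all 18111 genes tested. These correlations are across genes, which are not independent replicates. Of the genes called in both, 197 were higher in both where independent lists would share 24.0, 187 were lower in both against 21.8, and 1 moved in opposite directions. Averaged over genotype, 1634 genes were higher and 1455 lower with morphine (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Cdkn1a (2.11 ± 0.11), Nrros (1.26 ± 0.08), Tma16 (1.12 ± 0.07) and Fam214a (0.47 ± 0.03) were among the higher, and Sall1, a transcription factor gene of microglia (-0.62 ± 0.03), and Cx3cr1 (-0.55 ± 0.05) among the lower genes with the smallest p. With the serotonin score as a covariate the averaged count of 3089 became 501, and the correlation between genotypes 0.377.

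**Figure D2:**
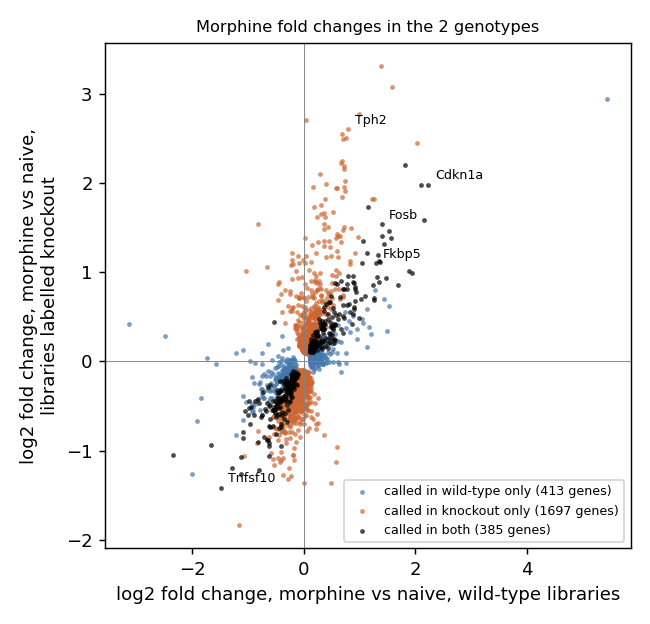
Log2 fold change of morphine against naive in wild-type libraries (horizontal axis) and in libraries labelled knockout (vertical axis), 1 point for each gene past adjusted p 0.05 in either, coloured by where it passed. Of the points in black, passed in both, 197 lie in the upper right and 187 in the lower left.

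No gene showed a morphine effect that differed between genotypes past the threshold. The interaction gave 0 genes by edgeR's quasi-likelihood test (smallest Benjamini-Hochberg adjusted p = 0.106; 2200 genes at an unadjusted p under 0.05) and 0 by limma-voom, while DESeq2's Wald test gave 107. Among the genes with the smallest p were Plxnb3 (-0.61 ± 0.10, adjusted p = 0.106), a semaphorin receptor gene, and the neuropeptide Y receptor gene Npy2r (0.81 ± 0.14, adjusted p = 0.106). Bdkrb2 (1.29 ± 0.24, adjusted p = 0.125), Btg2 (0.98 ± 0.20) and Cd44 (1.15 ± 0.25), both at an adjusted p = 0.143, were also among them. The larger number of called genes in the libraries labelled knockout is therefore not a tested difference in single genes. The interaction gave 56 genes without knockout morphine 3, 16 without wild-type morphine 3, and 1 without either wild-type naive 3 or wild-type morphine 4.

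**Figure D3:**
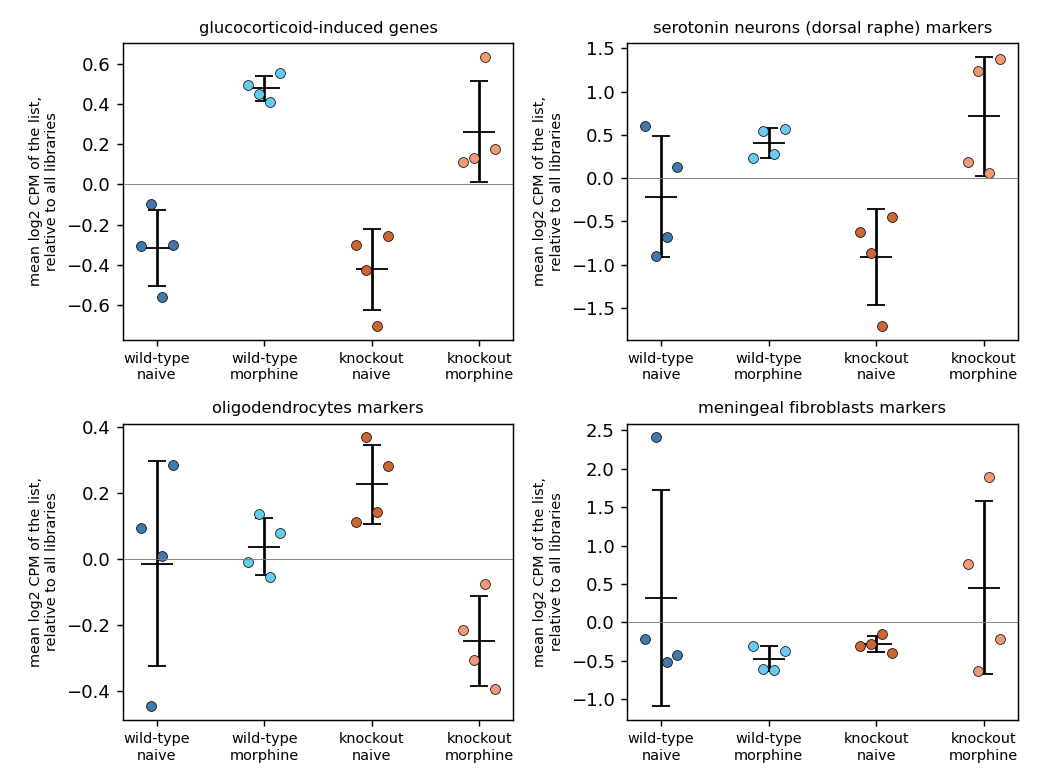
Score of 4 gene lists (vertical axes, mean log2 CPM of the members relative to all libraries) in each library, by group; points are libraries and bars the mean and SD of 4. Glucocorticoid-induced genes are higher in both morphine groups, the serotonin score has means of -0.91 and 0.71 in the libraries labelled knockout, and the highest meningeal scores are 2.41 (wild-type naive 2) and 1.90 (knockout morphine 3).

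Between naive libraries, those labelled knockout differed from wild type in a small set of genes. Higher were Rec8, a meiotic cohesin gene (3.54 ± 0.67), Ide, the insulin-degrading enzyme (1.07 ± 0.06), and Btaf1 (0.90 ± 0.07). Pantr1 (0.72 ± 0.07), Fgfbp3 (0.68 ± 0.10) and Acp1 (0.64 ± 0.09) were also higher. Lower were Hjurp, a centromere chaperone gene (-2.24 ± 0.17), Apoc1 (-1.67 ± 0.22), the dynein gene Dnah7b (-1.47 ± 0.08), Adhfe1 (-0.79 ± 0.08) and Ntn4 (-0.60 ± 0.08). In all, 80 genes were higher and 84 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group).

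Of 37 immediate early genes, 2 fell in naive libraries labelled knockout (8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0024; adjusted p = 0.912 with an estimated correlation), namely Btg2 (-0.69 ± 0.14) and Nr4a1 (-0.67 ± 0.14). Of 9 pericyte and smooth muscle markers, 1 fell, Pdgfrb (-0.39 ± 0.08; 1 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.963). The interferon list had a median of -0.43 and the oligodendrocyte list one of 0.23 with 0 members past edgeR's threshold over all genes (1 lower and 0 adjusted over the list alone), at camera adjusted p = 0.0001 and 0.000226, and both with an adjusted p = 0.912 with an estimated correlation. The serotonin markers had a median of -0.81 in the same comparison (camera adjusted p = 0.019; adjusted p = 0.912 with an estimated correlation) and the meningeal markers one of -1.21. Wild-type naive 2 stood apart in these lists, with scores of 1.04 for interferon, -0.45 for oligodendrocyte and 2.41 for meningeal markers, against at most 0.013 for interferon in the other wild-type naive libraries. The kappa opioid receptor gene Oprk1 was at 0.43 ± 0.11 (adjusted p = 0.0755), the only one of 8 opioid receptor and peptide genes past the threshold when adjusted over the list alone. The count of 164 genes was 80 without wild-type naive 2, 71 without wild-type naive 3, and 100, 68, 83 and 77 without knockout naive 1, 2, 3 and 4, and DESeq2's Wald test gave 376. Rec8 lost its call without any library but knockout naive 1 (edgeR adjusted p up to 0.106), and Btg2 without wild-type or knockout naive 2 or 3 (up to 0.0851). Nr4a1 lost its call without any but wild-type naive 1 or 4 (up to 0.122) and Pdgfrb without wild-type naive 1, 2 or 3 or knockout naive 1 or 4 (up to 0.0795).

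Under morphine, the genotype labels differed in many of the same genes. Ide (0.85 ± 0.06), Btaf1 (0.72 ± 0.07), Fgfbp3 (0.63 ± 0.11), Pantr1 (0.58 ± 0.07) and Acp1 (0.57 ± 0.09) were again higher, and Hjurp (-1.91 ± 0.17), Dnah7b (-1.17 ± 0.08) and Ntn4 (-0.53 ± 0.08) lower. Opn4, the melanopsin gene (1.00 ± 0.17), Pzp (0.99 ± 0.16) and Npy2r (0.57 ± 0.10) were higher, and Rtkn2 lower (-0.79 ± 0.14). In all, 46 genes were higher and 50 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group). Of these, 23 were higher and 21 lower in naive libraries too, where independent lists would share 0.203 and 0.232, and 0 moved in opposite directions.

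Of 31 glucocorticoid-induced genes, 0 passed edgeR's threshold over all genes and 5 were lower adjusted over the list alone in knockout morphine against wild-type morphine libraries, with a median of -0.21 (camera adjusted p = 8.62e-11; adjusted p = 0.974 with an estimated correlation). The oligodendrocyte markers had a median of -0.26 (camera adjusted p = 5.06e-07), the respiratory chain genes one of -0.06 (camera adjusted p = 1.34e-05) and the meningeal markers one of 1.24 (camera adjusted p = 0.0127), each with an adjusted p = 0.974 with an estimated correlation and 0 members past edgeR's threshold, also adjusted over the list alone. The meningeal score was 1.90 in knockout morphine 3, against 0.76, -0.63 and -0.22 in the other libraries of its group. Of 23 Wnt targets, 1 rose (3 adjusted over the list alone; camera adjusted p = 0.39), the adhesion receptor gene Cd44 (0.83 ± 0.18). Oprk1 was at 0.32 ± 0.11 (adjusted p = 0.322). The count of 96 genes was 57 without wild-type morphine 2, 61 without knockout morphine 2 and 49 without knockout morphine 4. It was 114 without knockout morphine 3. DESeq2's Wald test, and leaving out wild-type naive 2 and knockout morphine 3 together, gave still higher counts, listed below. Cd44 lost its call without any library but knockout morphine 2 (edgeR adjusted p up to 0.127), and Npy2r and Rtkn2 without knockout morphine 4 (0.0571 and 0.0502).

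Averaged over treatment, 124 genes were higher and 153 lower in the libraries labelled knockout (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 8 libraries against 8). Genes near Rgs20 were called more often: of 41 tested genes within 10 Mb, 8 passed, or 19.5%, against 1.49% of the rest (Fisher's exact test, two-sided p = 1.67e-07). That test takes neighbouring genes as independent, so its p is too small where calls cluster. Stretches picked afterwards as among the fullest were as full, such as 20 to 30 Mb on chromosome 12 (28.6%) and 40 to 50 Mb on chromosome 1 (21.6%). The latter lies on the chromosome of Rgs20, where 33 of 455 tested genes below 90 Mb were called, against 2 of 590 above. It is therefore not a separate comparison. Near Rgs20, Mcmdc2 (-3.79 ± 0.25) and Adhfe1 (-0.64 ± 0.06) were lower, and Vxn (0.50 ± 0.04) and Lactb2 (0.46 ± 0.05) higher. Oprk1, named here after its values were seen, lies at 5588466 to 5606131 on chromosome 1 and was higher by 0.37 ± 0.08 (adjusted p = 0.0169). As a list, the genes near Rgs20 did not stand apart in 1 direction (camera adjusted p = 0.902, higher, while the median of -0.0071 and mean of -0.074 were below 0), with 5 higher and 3 lower (6 and 7 adjusted over the list alone). Further along chromosome 1, Dnah7b, at 46066315 to 46373546, was at -1.32 ± 0.05 and Hjurp, at 88262471 to 88277633, at -2.08 ± 0.12, while Pantr1 was at 0.65 ± 0.05.

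Most called genes lay on other chromosomes. Chromosome 7 held 36 (2.65% of its tested genes). Chromosome 1 held 35, or 3.35% of its tested genes, against 1.42% of the rest (Fisher's exact test, two-sided p = 1.20e-05, which takes genes as independent). There were 24 on chromosome 12 (3.74%) and 22 each on chromosomes 14 (3.45%) and 5 (1.98%). The fullest stretches of 10 Mb were 10 to 20 Mb on chromosome 7, with 16 called genes (13.0%), and 20 to 30 Mb on chromosome 12, with 12 (28.6%). On chromosome 19, Ide, at 37268743 to 37337852, was higher by 0.96 ± 0.05 and Btaf1, at 36926079 to 37012752, by 0.81 ± 0.05. Between them, Cpeb3 was at 0.06 ± 0.03 (adjusted p = 0.624) and March5 at 0.01 ± 0.03 (adjusted p = 0.985), named after their values were seen. Ccnb1ip1 on chromosome 14 was at 3.20 ± 0.33 and Ntn4 on chromosome 10 at -0.57 ± 0.06. Of 271 called genes with a position, 161 (59.4%) had another called gene within 1 Mb, against a median of 87 in 10000 random sets of tested genes and a highest value of 126 (share of sets as high 0.0001, the smallest these sets can give). Of 160 called between naive libraries, 66 had one, against a random median of 34, and of 94 between morphine libraries 37 against 12. The genes called with morphine were not closer together than random sets, at shares of 0.763 in wild-type libraries and 0.334 in libraries labelled knockout. The averaged genotype count of 277 was 434 by DESeq2's Wald test.

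**Figure D4:**
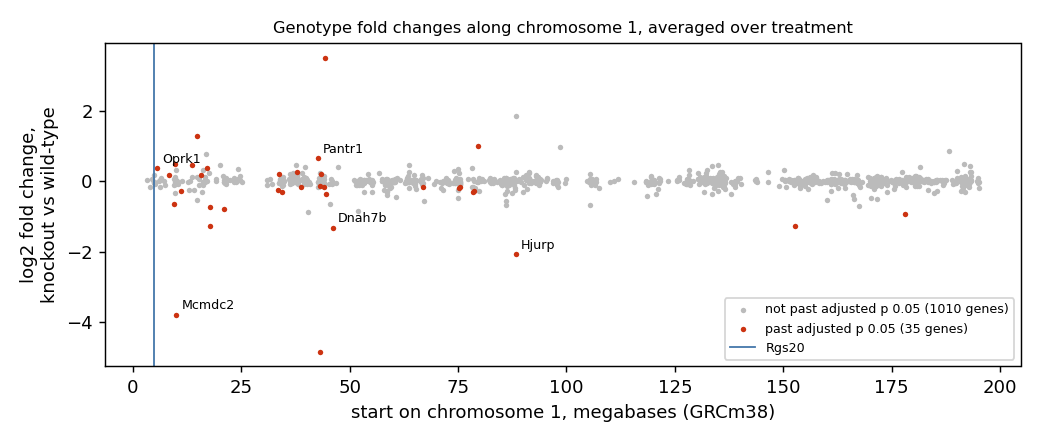
Log2 fold change of libraries labelled knockout against wild-type libraries, averaged over treatment (vertical axis), by start on chromosome 1 in megabases of GRCm38 (horizontal axis), 1 point per tested gene, in red where past adjusted p 0.05; the line marks Rgs20. Of the 35 red points, 33 lie below 90 Mb, a bound chosen after the values were seen.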

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

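The tests of exchanged labels, of continuing transcription, of strain DNA on chromosome 1 and elsewhere, of gene density, of shuffled covariates and of the ratio without single libraries were chosen after the results they concern were seen. Single libraries far from their group were looked for with Dixon's ratio, the gap to the nearest other library divided by the group's range, in 660 sets of 4 libraries. A ratio above the 95% critical value was found in 41 sets, where about 33 are expected by chance, 1 in 20. Among list scores there were 15 of 160 against 8 expected, among gene levels 25 of 480 against 24, and among library measures 1 of 20 against 1. Single entries for genes are therefore near what chance gives, and the list scores lie above it but share libraries and genes.

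Among the list scores, wild-type naive 2 stood above its group for meningeal fibroblast markers (2.41, ratio 0.895), interferon response genes (1.04, ratio 0.901) and extracellular matrix genes (0.73, ratio 0.951). Heat shock genes were low in wild-type naive 3 (-0.23, ratio 0.976) and glutamatergic neuron markers in wild-type naive 4 (-0.24, ratio 0.942). RGS genes were high in wild-type morphine 1 (0.098, ratio 0.901). In knockout naive 2, endothelial markers were high (0.27, ratio 0.877) and choroid plexus markers low (-0.23, ratio 0.914). Extracellular matrix genes were high in knockout naive 3 (0.020, ratio 0.980) and dopamine neuron markers in knockout naive 1 (-0.036, ratio 0.836). Knockout morphine 3 was high for glucocorticoid-induced genes (0.63, ratio 0.877) and low for opioid signalling genes (-0.038, ratio 0.963). Knockout morphine 1 was low for ion channel genes (-0.077, ratio 0.958) and for motor and cholinergic neuron markers (-0.36, ratio 0.838), and knockout morphine 2 for microglia markers (-0.19, ratio 0.835). The share of ambiguous reads was low in wild-type naive 3 (2.19%, ratio 0.839).

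Among the gene levels, in CPM, wild-type naive 1 stood apart for Maob (71.9, ratio 0.835), Nkd1 (14.6, ratio 0.840), Rec8 (1.05, ratio 0.864) and Fgfbp3 (4.66, ratio 0.888). Wild-type naive 2 did so for Clec14a (5.83, ratio 0.855) and Opalin (25.8, ratio 0.939), and wild-type naive 4 for Xbp1 (75.7, ratio 0.956) and Vip (19.7, ratio 0.959). In the wild-type morphine group, library 3 differed for Tma16 (25.7, ratio 0.909) and Ccnb1ip1 (0.113, ratio 0.915), and library 4 for Fosl2 (23.2, ratio 0.847) and Cldn5 (7.31, ratio 0.916). In the knockout naive group, library 1 differed for Gng2 (211, ratio 0.946) and Rec8 (10.8, ratio 0.926), and library 2 for Erbb3 (35.8, ratio 0.935) and Dnah7b (10.5, ratio 0.871). Library 3 of that group differed for Wdfy1 (59.1, ratio 0.986), and library 4 for Vip (25.8, ratio 0.949) and Lactb2 (21.4, ratio 0.853). In the knockout morphine group, library 1 differed for Fosl2 (12.2, ratio 0.842) and Erbb3 (24.4, ratio 0.911), and library 2 for Adi1 (29.3, ratio 0.836). Library 3 there differed for Hjurp (81.4, ratio 0.880) and Ninj2 (2.21, ratio 0.925), and library 4 for Vip (52.0, ratio 0.926).

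By camera's interaction test with a preset correlation, 12 lists stood apart from other genes. The oligodendrocyte markers (camera adjusted p = 1.12e-09, median -0.53), the respiratory chain genes (7.90e-05, median -0.072), the glucocorticoid-induced genes (0.00623, median -0.19) and the heat shock genes (0.0294, median -0.070) had lower values of the interaction than other genes. The serotonin markers (camera adjusted p = 0.00101, median 1.32), the meningeal markers (0.00111, median 2.45) and the extracellular matrix genes (0.00111, median 0.34) had higher ones. So did the interferon (camera adjusted p = 0.00940, median 0.48), cerebellum (0.0177, median 0.39), ribosomal (0.0286, median 0.040), inflammation (0.0294, median 0.12) and ependymal lists (0.0414, median 0.33). None passed with an estimated correlation (smallest adjusted p = 0.823) or by fry (smallest adjusted p = 0.643), so a different response of these lists is not shown, and 0 genes passed the interaction by edgeR's quasi-likelihood test or limma-voom, with 2200 at an unadjusted p under 0.05 and 107 by DESeq2's Wald test. The meningeal entry follows wild-type naive 2 and knockout morphine 3, the libraries with the highest scores of those markers. The same libraries were highest for extracellular matrix (0.73 and 0.40) and inflammation genes (0.50 and 0.28), and wild-type naive 2 for interferon genes (1.04).

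Rgs20 was not lower in the libraries labelled knockout. Exchange of labels between single libraries is argued against by the genes near Rgs20. Chosen without the library in question, they placed 16 of 16 libraries on the side of their own label. The labels of the other libraries set these genes and their direction, so an exchange of both genotypes as a whole would give the same outcome. The placement does not show the state of Rgs20 itself. Reads of other genes stay open. Of the 50-base words of Rgs20 transcripts, 4.18% occur in other genes, under the bound of 10% set beforehand, but that bound covers shared sequence only. Atp6v1h, which overlaps the start of Rgs20 on the other strand, had a mean count of 6232 against 474 for Rgs20, and the kit does not mark the strand. The genes share only the stretch from 5070018 to 5070285, and the mean of 6232 is for all of Atp6v1h, so it does not measure reads from that stretch. Where strand is ignored in counting, HTSeq sets reads that fall on both genes apart as ambiguous, and such reads stayed out of the counts. The strand setting is not given. Reads outside genes were 11.3% (wild-type morphine 4) to 12.7% (knockout naive 1), which is low for a count by strand with this kit. Reads of Atp6v1h counted as Rgs20 in that stretch were not measured. Transcription of the targeted allele that continues, without a deleted part, may explain the counts and stays open: the averaged level had a lower 95% bound of 88.6% of wild type, and counts per exon were not analysed here. Whether protein was lost cannot be told from these counts.

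More genes were called with morphine in the libraries labelled knockout than in wild-type libraries, at a ratio of 2.61. Depth is argued against, since the ratio was 2.89 with all libraries thinned to the smallest total, and so is meningeal tissue in 2 libraries, since it was 4.81 without wild-type naive 2 and knockout morphine 3. The counts depended on single libraries: 2082 became 1037 without knockout naive 2, 1302 without knockout naive 4, 1248 without knockout morphine 2 and 1301 without knockout morphine 4. The wild-type 798 became 1252 without naive 4, 378 without naive 3, 493 without naive 2, and 427, 389 and 493 without morphine 1, 2 and 4. Refitted without each library, the ratio ranged from 1.57 (knockout morphine 2) to 5.10 (wild-type naive 3). For more raphe tissue in the knockout morphine punches, the ratio with the serotonin score as a covariate was 0.838, under the bound of 1.5 set beforehand for that explanation, but 53 of 60 shuffled covariates with the same group means also fell under 1.5 and 44 were at or under the real value. The covariate overlaps with the groups and widened the standard errors 1.54 times while keeping 94.3% of the fold changes of the called genes at the median. Its ratio therefore decides nothing, and a difference in raphe tissue cannot be told apart from a larger response. The mean serotonin score was -0.91 in knockout naive against -0.21 in wild-type naive libraries, and 0.71 in knockout morphine against 0.41 in wild-type morphine libraries. Low scores in knockout naive libraries thus also enter the contrast, with SDs of up to 0.70 within groups. The shuffled covariates were added after the ratio was seen, and a stronger morphine response in these mice stays open.

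The genes called between genotype labels lay close together along the genome. Gene density alone is argued against: random sets of tested genes had a neighbour within 1 Mb for a median of 32.1% of their genes, against 59.4% of the called genes. Most lay on other chromosomes than that of Rgs20, with 36 on chromosome 7, 24 on chromosome 12 and 22 each on chromosomes 5 and 14, against 35 on chromosome 1. By share of tested genes, chromosome 1 had 3.35% called against 1.42% of the rest (Fisher's exact test, two-sided p = 1.20e-05). Chromosomes 12 and 14 had 3.74% and 3.45%. Outside chromosome 1, 141 of 236 called genes had a called neighbour within 1 Mb, and the share of random sets as high was 0.0001, the smallest they can give. Stretches of DNA of another mouse strain there may be the source and would give such neighbours, but they would not be linked to the targeted locus, and no sequence variant was examined. On chromosome 1, DNA of another strain carried along with the locus may contribute and stays open. In the test written for it, 20 of 35 called genes had a called neighbour, against a median of 15 in random sets of that chromosome (share as high 0.0953), so it missed its bound of 0.05. That bound was ill chosen, since a long linked stretch needs no neighbours within 1 Mb. Of genes within 10 Mb of Rgs20, 19.5% were called against 1.49% of the rest (Fisher's exact test, two-sided p = 1.67e-07). Fisher's test takes neighbouring genes as independent, which the clustering of the calls goes against. A stretch on chromosome 12, picked afterwards as among the fullest, was as full (28.6%). Reading the explanation as open was decided after the share was seen. Without overlap between 8 and 8 libraries were 87 genes, where chance gives 2.81, or 0.0155% of genes. Shared regulation of neighbouring genes was not tested, and local effects of the targeted locus stay open for its neighbours.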

How the results depend on the processing

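The covariate fits, leaving out wild-type naive 2 and knockout morphine 3 together, and thinning were chosen after the data were seen. Where a result moved, the cause was not tested unless named. DESeq2's size factors kept all 170 followed gene values, each a gene in a comparison, on their side of the threshold, and so did the stricter filter for its 169, with 1 change of sign. Limma-voom kept 166, 1 surrogate variable 160, no filter 159, the replicate block 157, thinning 156 and the groups compared alone 127 of 146. DESeq2's Wald test kept 163 and called 7 more. Without wild-type naive 2 and knockout morphine 3, 153 were kept, 12 lost and 4 gained. The serotonin score kept 114, with 49 calls lost and 7 signs changed, and both scores kept 87, with 78 lost and 5 signs changed.

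Counts of called genes moved by over 1.5 times as follows. DESeq2's Wald test gave 1242 with morphine in wild-type libraries, 376 between genotypes in naive and 202 in morphine libraries, 107 for the interaction and 434 for the averaged genotype, with an agreement of the morphine fold changes of r = 0.470. In simulated counts, 14.3% of its calls were false for the wild-type comparison. The 8 wild-type libraries alone gave 410. With 1 surrogate variable the counts were 481 in wild-type and 104 between naive libraries, and 1 for the interaction, which was also 1 with no filter. Thinning gave 96 between naive libraries, with fewer counts as the cause by construction.

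With the serotonin score as a covariate, morphine gave 365 genes in wild-type libraries, 306 in libraries labelled knockout and 501 averaged, and the agreement was 0.377. With the meningeal score as well, the counts were 396, 3 and 282, and 63 and 32 between genotypes in naive and morphine libraries. Without wild-type naive 2 and knockout morphine 3 they were 104 and 236, and 64 for the interaction. Values of morphine in libraries labelled knockout that changed sign with the serotonin score were Tph2 (-0.10), Slc6a4 (-0.10), Slc18a2 (-0.038), Fev (-0.41), Sst (-0.019) and Chrna6 (-0.046), by construction of a score made from serotonin genes for the markers among them, and Oprm1 (0.092). With both scores these were Tph2 (-0.11), Slc6a4 (-0.17), Fev (-0.32), Lhx4 (-0.038) and Oprm1 (0.21). Oprm1, never called, was also at 0.013 without both libraries, and in wild-type libraries at -0.0026 under the stricter filter.

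The replicate numbers did not pair the libraries: 24 same-numbered pairs had a mean r of -0.03 (-0.28 to 0.13, 3 over 0.1), and 2 libraries correlated best with their own number. With the replicate block the counts were 512 with morphine in wild-type libraries and 89 between naive libraries. Of 40 lists, camera called 22 and 12 with morphine in wild-type libraries and libraries labelled knockout and 6 and 5 between genotypes in naive and morphine libraries; with an estimated correlation each became 0, and by fry 3, 9, 0 and 0.

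Leaving out each library in turn gave 378 to 1252 genes with morphine in wild-type libraries, 1037 to 2260 in libraries labelled knockout, 68 to 210 between naive and 49 to 114 between morphine libraries. The interaction gave 0 to 56, the averaged genotype 216 to 298 and averaged morphine 2399 to 3302. The agreement was 0.536 to 0.696. Rgs20 ranged from -0.073 to 0.011 in naive and from -0.16 to -0.062 in morphine libraries. Oprm1 ranged from -0.091 to 0.059 in wild-type libraries and from -0.086 to 0.015 in libraries labelled knockout. Of 1552 gene values, 1388 kept their side, 154 lost their call, 4 gained one and 6 changed sign. At these depths, edgeR's quasi-likelihood test recovered 50% to 60% of the smallest simulated fold changes, set in genes with a mean above 1 CPM.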

Other observations

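The comparison of fits without single libraries and the description of sample structure below were made after the results were seen. Other divisions of the same libraries into groups of the same sizes were tested with the same count of genes. Of 35 splits of the wild-type libraries, 1, the real one, gave as many genes as the real 798, and the highest other gave 3. For morphine in libraries labelled knockout 1 of 35 did (2082, highest other 1), for genotype in naive libraries 1 of 35 (164, highest other 1) and for genotype in morphine libraries 1 of 35 (96, highest other 8). The real split gave the most genes in each case, and 1 of 35 is the smallest share these splits can give. Splits that mix the groups carry a real difference into the spread, which lowers their counts. Their low counts alone therefore do not exclude chance. For morphine averaged over genotype, 1 of 100 drawn splits, the real one, gave as many as 3089, with 304 the highest other. The same limit applies there.

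For the averaged genotype, 2 of 100 splits gave as many genes as the real 277, and the other had 748. That split set wild-type naive 4, knockout naive 2, 3 and 4, wild-type morphine 2, 3 and 4 and knockout morphine 3 against the rest. It was the highest of the drawn splits. Most knockout naive and most wild-type morphine libraries stood on its first side, so it largely follows the combination of genotype and treatment. The list scores that differed most between its sides, picked from 40, were those of the respiratory chain by 1.36 SD (0.045 and -0.045), neuron markers by 1.22 SD and oligodendrocyte markers by 1.21 SD. The respiratory chain and oligodendrocyte lists were also among those called by camera's interaction test with a preset correlation. For the interaction, all 100 splits gave at least the real count of 0, and the highest gave 3089, because exchanging treatment within 1 genotype turns the interaction into the averaged morphine effect. With a real count of 0, every split gives at least as many, so the splits say nothing about the interaction.

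The number of interaction calls depended on knockout morphine 3. Without that library, 56 genes passed edgeR's quasi-likelihood test (16 higher, 40 lower), and without it and wild-type naive 2, 64 passed (18 higher, 46 lower), 48 of them shared. All kept the sign they had with all libraries. Plxnb3 was at -0.67 ± 0.10 without knockout morphine 3 (adjusted p = 0.0273) and -0.59 ± 0.07 without both libraries (adjusted p = 0.00394). Npy2r was at 0.85 ± 0.15 (adjusted p = 0.0273) and 0.84 ± 0.15 (adjusted p = 0.0314). Leaving out a library because of its scores does not give an independent test.

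A larger share of raphe tissue in the morphine punches might also raise glucocorticoid-induced genes. In wild-type libraries the values go against it, as far as the serotonin score tracks such tissue. The list's median log2 fold change was 0.72 without and 0.73 with that score as a covariate, 102% of its value. The 798 called genes of that comparison kept 93.9% at the median, so this was not particular to the list. In libraries labelled knockout the median went from 0.81 to 0.73 and the calls from 24 to 3, with a covariate that overlaps with the groups. That fit decides nothing there, and no shuffled covariates were run for the list.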
